A study of Drosophila melanogaster with 12 samples.

How the data were processed

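The study measured 2 histone marks by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in S2 cells, an established Drosophila melanogaster line of embryonic origin. Per the labels, cells were treated for 5 days with double-stranded RNA against GFP, a control sequence, or against KDM4A. Chromatin was crosslinked for 10 min with 1% paraformaldehyde, sheared in 30 sonication cycles and precipitated with 5 µg of an antibody to H3K9me3 or H3K36me3, and libraries were made with an Illumina TruSeq kit, per the labels. The labels list 12 libraries in 6 groups of 2: GFP RNAi and KDM4A RNAi, each with H3K9me3 ChIP, H3K36me3 ChIP and input. Libraries are numbered 3 and 4 in every group, and nothing in the labels says whether these came from separate cultures.

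The authors deposited 2 tables, 1 for each antibody, with 1 row per repeat family or part of a family. Each row gives a linear enrichment ratio for each RNAi treatment, which is a mean per the file headers. Bowtie and MACS2 are named in the submitters' processing notes, without a version or a role. The genome build, the repeat library, the treatment of reads that map to many copies, the denominator of the enrichment and the scaling for depth are not given in the sources used here. Which libraries entered each mean is also not stated. The deposited values are given to 3 decimals. Per-library values, input values and read counts were not analysed here. The depth behind each value is therefore unknown, and no value of a repeat has a standard deviation, a confidence interval or a limit of detection. The knockdown itself was not measured in the tables, so the level of KDM4A was not checked.

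The tables give names and types of repeats and no genomic coordinates, so positions in the genome are not stated. Of the 203 repeats in the H3K9me3 table, 199 were also in the H3K36me3 table. The 4 others were GYPSY7_LTR, GYPSY8_LTR, GYPSY9_LTR and INVADER5_LTR. Names were identical for 185 repeats. The 14 tandem repeats carry an added word in the H3K9me3 table (such as dodeca repeat for ACCGAGTACGGG), and were matched after it was removed. The 7 types were those of the tables. Many LTR retrotransposons appear in separate rows for the internal part and its terminal repeat, and 51 elements had both parts in both tables.

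For each repeat and mark the log2 ratio of the KDM4A RNAi mean to the GFP RNAi mean was computed with no pseudocount, since every value was above 0. The planned test across replicates could not be run on 1 mean per treatment, so no p-value is reported and repeats are called higher or lower as description only. Repeats do not stand in for replicates of a treatment. The 95% intervals of the closing section come from a bootstrap of 10000 draws with replacement over repeats, or over the 51 elements with both parts. They describe the spread over repeats and carry no error between libraries or cultures. Drawing all rows of 1 element together (134 elements for the 189 repeats) gave 0.31 to 0.56 for rho and 1.06 to 1.13 for the slope. Each table was analysed alone, since the scaling of one relative to the other is unknown. The spread of the log2 ratios over repeats, and the difference between the 2 parts of 1 element, are given as a measure of scatter. The median log2 ratio of each type was set against 10000 random lists of the same size, drawn from the same 5 equal-sized bins of mean level (the mean of both columns). The changes of the 2 marks were compared with Pearson's r and Spearman's rho across repeats, which are not independent. Repeats were put in 4 equal-sized bins of the mean of both columns, so that neither treatment alone set the order.

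The rule for naming repeats was fixed before the data were examined. Per mark it took the 5 largest log2 ratios in each direction, the 5 highest mean levels, and a fixed list of satellites, ribosomal DNA and telomeric elements, of which 8 rows were found in the tables (ribosomal DNA, AATAT, AAGAG, dodeca, HeT-A, TAHRE and both TART rows). This gave 22 repeats for H3K9me3 and 21 for H3K36me3. Repeats outside this rule were chosen after their values were seen. These are AAAAG, AAGGAG, AAACAC, AACAC, 1.688, ACCAGTACGGG and AAGAC in the H3K36me3 table, AAAAG, AAGAGG, 1.686, 1.688 and AAGAGAAGAGAG in the H3K9me3 table, GYPSY3_LTR, R1-2_DM and FROGGER_LTR where they are named for the other mark, I_DM, the histone genes, R1_DM, R2_DM, MDG1_I, DM297_I and BLOOD_I. The internal parts GYPSY11_I, FROGGER_I and GYPSY3_I were also chosen after their values were seen. The fixed lists of heterochromatic and fourth-chromosome genes matched no row.

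The alternatives were a pseudocount of 1, only repeats at or above the median level, columns centred on their median, a minimum change of 1.5 times, the linear scale, means or sums in place of medians, 2 level bins in place of 4, and leaving out the 2 farthest repeats. Leaving out the tandem repeats, the match of names without the added word, centring before the medians per type and the directions of both marks, and leaving out the 1 or 2 elements of most weight on the covariance were added after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The functions were tested on simulated data made from the real levels with scatter of 0.1 (SD, log2) and 20 repeats raised by 1 log2 unit. All 20 were recovered at the minimum of 1.5 times in both simulated tables, of 203 and 199 repeats, and 0 repeats were called lower. The SD of the real log2 ratios over repeats was larger, 0.305 for H3K9me3 and 0.182 for H3K36me3. The simulation therefore checked the functions, not how reliably changes are found in the real data.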

Results

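H3K9me3, a histone mark of heterochromatin, and H3K36me3, a mark of transcribed gene bodies, were measured by ChIP-seq over repeated sequences in Drosophila S2 cells after RNAi against GFP or against KDM4A, a Jumonji-domain histone demethylase. The comparison asked how depletion of KDM4A altered the 2 marks over the repeats of heterochromatin. Values were mean enrichment per repeat family or part of a family, 1 per treatment, for 203 repeats with H3K9me3 and 199 with H3K36me3. The labels list 2 libraries per treatment and antibody, but the tables hold 1 mean for each and do not state which libraries entered it, so no difference below has a replicate check, and the depth is unknown. In GFP RNAi cells the median enrichment was 2.32 for H3K9me3, with 172 of 203 repeats above 1. For H3K36me3 it was 0.898, with 80 of 199 above 1.

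H3K9me3 enrichment differed most between treatments at simple-sequence satellites, the short tandem repeats of heterochromatin. AAGGAG had the highest H3K9me3 value of any repeat in GFP RNAi cells, 8.19, and was at 1.37 in KDM4A RNAi cells, 6.0-fold lower. AAACAC was at 0.774 and 0.280, AACAC at 2.04 and 0.815, and AAGAC at 2.46 and 1.08, which are 2.76-, 2.5- and 2.29-fold lower after KDM4A RNAi. With a pseudocount of 1 the log2 ratios of these 3 shrank from -1.47, -1.32 and -1.19 to -0.47, -0.74 and -0.74. The fifth of the largest decreases was at GYPSY8_LTR, the terminal repeat of a gypsy-family retrotransposon, with 6.60 and 4.04. Its internal part GYPSY8_I, the repeat with the highest mean level, was at 6.50 and 6.73.

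The satellites did not move together. Of the 14 tandem repeats, 9 were lower and 5 higher in H3K9me3 after KDM4A RNAi, with log2 ratios from -2.58 to 0.82. Their median of -0.07 lay at percentile 17.2 of random lists matched by level, whereas their mean was -0.39. The matching is incomplete, since 6 of the 14 lay below the lowest level of any other type. The 5 higher repeats included AATAG (0.176 and 0.310, the largest relative increase of any repeat, with a log2 ratio of 0.82 that a pseudocount of 1 brought to 0.16), AATAT (0.928 and 1.18), and the G+C-rich ACCAGTACGGG (3.67 and 5.30) and dodeca, ACCGAGTACGGG (3.17 and 3.73). The AAGAG satellite was low in both treatments, at 0.205 and 0.190. The 1.688 satellite, a pericentromeric repeat of the X chromosome, was at 0.967 and 0.943.

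**Figure D1:**
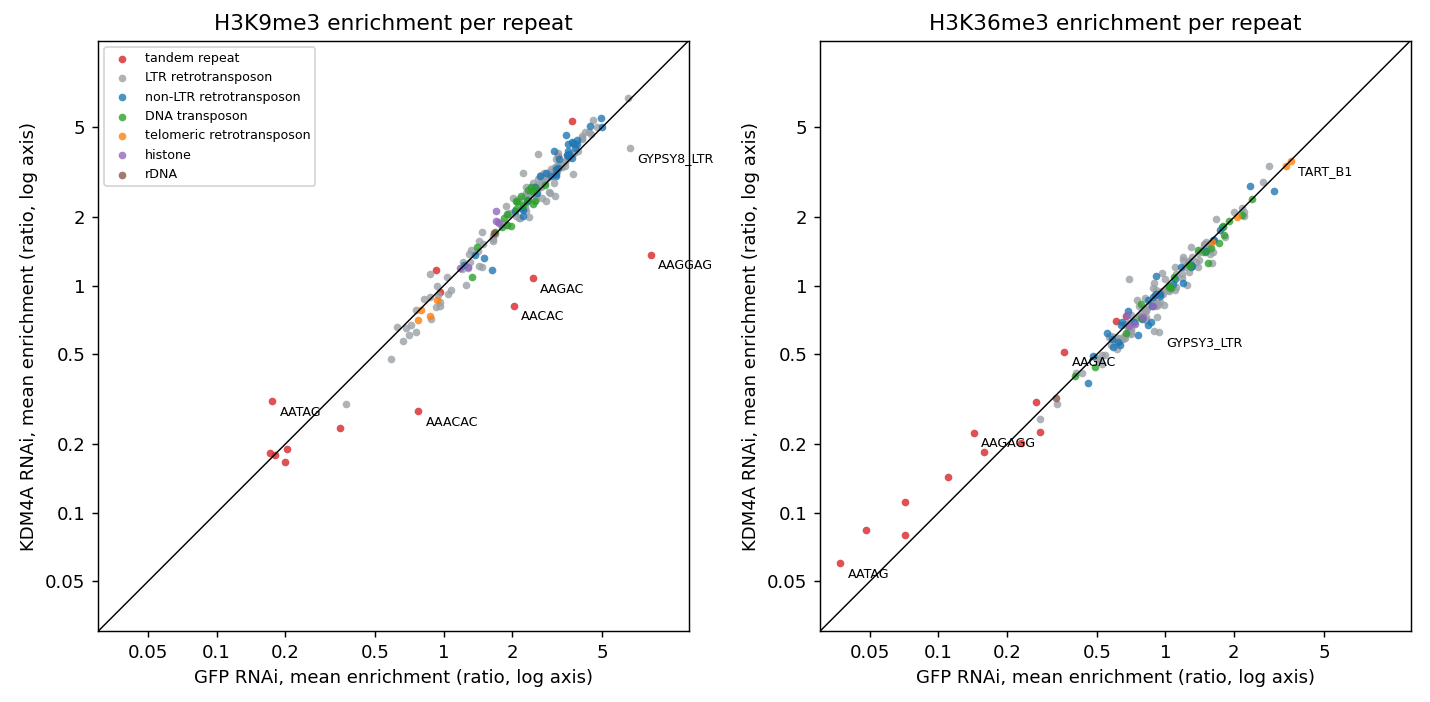
Mean enrichment of each repeat after KDM4A RNAi (y axis) against GFP RNAi (x axis), as ratios on log axes, for H3K9me3 (left) and H3K36me3 (right). Each point is 1 repeat, coloured by type, and the line marks equal values; AAGGAG, AAACAC, AACAC and AAGAC lie far below the line for H3K9me3, and most low satellites lie above it for H3K36me3.

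H3K9me3 over transposons was slightly higher after KDM4A RNAi in most rows, as it was in 64.5% of all repeats. It was higher at 80 of 122 LTR retrotransposon rows, 26 of 36 non-LTR retrotransposons and 15 of 21 DNA transposons. After centring these counts were 70, 22 and 12. The median log2 ratios were small, 0.05, 0.07 and 0.07, and 0.02, 0.04 and 0.04 after centring. These medians lay at percentiles 67.0, 34.2 and 81.7 of random lists of matched level, so none of the 3 types stood apart. Centring shifts every log2 ratio of a mark by the same amount, so it leaves such percentiles unchanged. The largest increases among transposons were at GYPSY11_LTR (2.61 and 3.82), FROGGER_LTR (2.25 and 3.14) and R1-2_DM (3.46 and 4.61), a relative of the R1 element that inserts into ribosomal RNA genes. The other repeats with the highest levels were also above their GFP RNAi value: DMRT1A at 4.93 and 5.50, DIVER2_I at 4.53 and 5.35, and G7_DM at 4.99 and 5.01, which turned to a log2 ratio of -0.02 when columns were centred. The I element (I_DM), a non-LTR retrotransposon, stood apart from its type with 1.63 and 1.17.

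The telomeric retrotransposons, which maintain fly chromosome ends, were low in H3K9me3 and lower after KDM4A RNAi at all 4 rows. HeT-A (HETA in the table) was at 0.798 and 0.785, TAHRE at 0.939 and 0.864, TART at 0.774 and 0.706, and TART_B1 at 0.868 and 0.736. Their median log2 ratio of -0.13 lay at percentile 40.0 of random lists of matched level, so it did not stand apart from other repeats at this level. Of the 5 histone genes, which lie in a tandem array, 4 were higher, led by His3 at 1.70 and 2.14. After centring 3 were higher and 2 lower. Their median, 0.11 as deposited, lay at percentile 95 of random lists drawn from separate repeats, which centring does not alter. Genes of 1 array are not independent, so this percentile may overstate how far they stood apart. Ribosomal DNA was at 1.67 and 1.70.

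Over all repeats H3K9me3 was higher in 131 and lower in 72, with a median log2 ratio of 0.04 and an interquartile range from -0.05 to 0.12. After centring of each column on its median the numbers were 113 and 90. In 51 elements with both an internal part and a terminal repeat, the log2 ratios of the 2 parts differed by a median of 0.14, and they had the same sign in 29 of 51. Of 179 transposon rows, 116 differed between treatments by less than this median. A difference of 2 log2 ratios carries the scatter of both, so this count does not show that these rows lie within scatter. A change of at least 1.5 times was seen at 6 repeats, of which 5 were lower (the 4 satellites and GYPSY8_LTR) and 1 higher (AATAG).

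**Figure D2:**
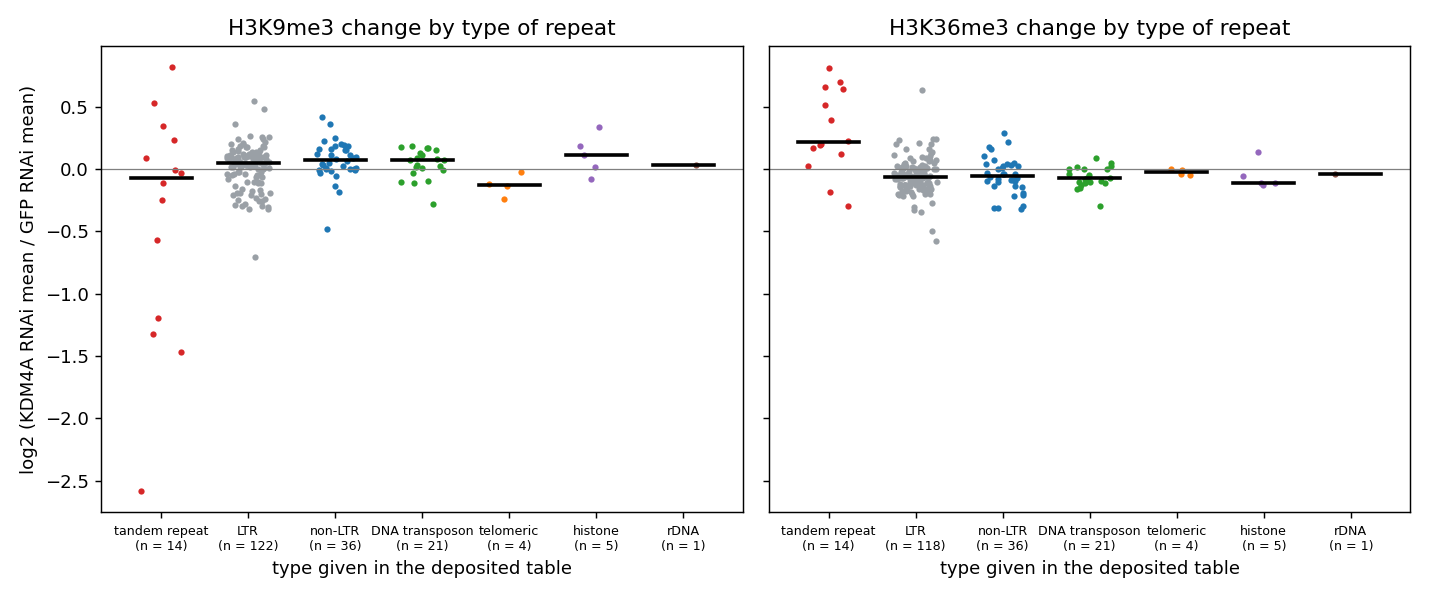
Log2 ratio of the KDM4A RNAi mean to the GFP RNAi mean (y axis) by type of repeat (x axis, with the number of repeats) for H3K9me3 (left) and H3K36me3 (right). Points are repeats, black bars are medians over repeats, not replicate means, and no error bars are drawn; tandem repeats spread from -2.58 to 0.82 for H3K9me3 and have a median of 0.22 for H3K36me3.

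The H3K9me3 difference followed the level of the mark. Among the 51 repeats with the lowest mean level, 14 were higher and 37 lower, with a median log2 ratio of -0.10. Among the 51 with the highest level 46 were higher and 5 lower, with a median of 0.10. The lowest 51 held LTR retrotransposons with little H3K9me3 in these cells, such as MDG1_I (0.759 and 0.623), DM297_I (0.661 and 0.573) and BLOOD_I (0.882 and 0.715). These examples were all lower, but not every repeat at such levels was. Of the 23 repeats under a level of 1, without the tandem repeats, 17 were lower and 6 higher.

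H3K36me3 was higher after KDM4A RNAi at 12 of 14 tandem repeats. The largest increases were at satellites with very little of the mark: 1.686 (0.048 and 0.084), AATAG (0.037 and 0.060), AAGAGG (0.143 and 0.225) and AAGAGAAGAGAG (0.071 and 0.111). AAGAG was at 0.110 and 0.144, and AAGAC at 0.359 and 0.512. The 2 lower members were AATAT (0.230 and 0.202) and 1.688 (0.280 and 0.228). The median log2 ratio of the type, 0.22, was above that of all 10000 random lists, whose median was -0.07. The matching is incomplete, since 9 of the 14 lay below the lowest level of any other repeat, and in linear units the 14 differences ran from -0.052 to 0.153. With a pseudocount of 1 the log2 ratio of 1.686 shrank from 0.81 to 0.05 and that of AATAG from 0.70 to 0.03.

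H3K36me3 over transposons was slightly lower in the deposited values, at 82 of 118 LTR retrotransposon rows, 22 of 36 non-LTR retrotransposons and 15 of 21 DNA transposons. Their medians were -0.06, -0.05 and -0.08 on the log2 scale, and all 3 turned positive, to 0.03, 0.04 and 0.01, when columns were centred. These medians lay at percentiles 18.6, 53.9 and 8.28 of random lists of matched level, with or without centring. The largest decreases were at GYPSY3_LTR (0.938 and 0.627), GYPSY9_I (0.892 and 0.631), INVADER5_I (1.60 and 1.26), ACCORD2_LTR (0.916 and 0.729) and BS4_DM (0.755 and 0.604). GYPSY11_LTR differed the other way, with 0.688 and 1.07. Over all repeats 67 were higher, 130 lower and 2 equal, and after centring 124 were higher and 75 lower. Centring subtracts the same -0.089 from every H3K36me3 log2 ratio, so the reversals after centring follow from that shift. The 2 parts of 1 element differed by a median of 0.09, and 89 of 175 transposon rows differed between treatments by less. As for H3K9me3, such a count does not show that these rows lie within scatter. The median log2 ratio was -0.08 for the 50 repeats with the lowest mean level and -0.02 for the 50 with the highest. A change of at least 1.5 times was seen at 5 repeats, all higher: 1.686, AATAG, AAGAGG, AAGAGAAGAGAG and GYPSY11_LTR.

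The highest H3K36me3 levels were at the telomeric TART_B1 (3.56 and 3.55) and TART (3.40 and 3.37), followed by GYPSY5_I (2.86 and 3.37), FW3_DM (3.02 and 2.62) and BEL_I (2.69 and 2.86). HeT-A was at 1.60 and 1.56 and TAHRE at 2.07 and 2.00. As deposited all 4 telomeric rows were below their GFP RNAi value by less than 0.05 log2 units, and after centring all 4 were above it, by 0.04 to 0.09. Ribosomal DNA was low at 0.330 and 0.320, a difference that also changed sign after centring. Of the 5 histone genes 4 were lower, with a median log2 ratio of -0.11, and His3 was the exception at 0.680 and 0.746; after centring 2 were higher and 3 lower.

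**Figure D3:**
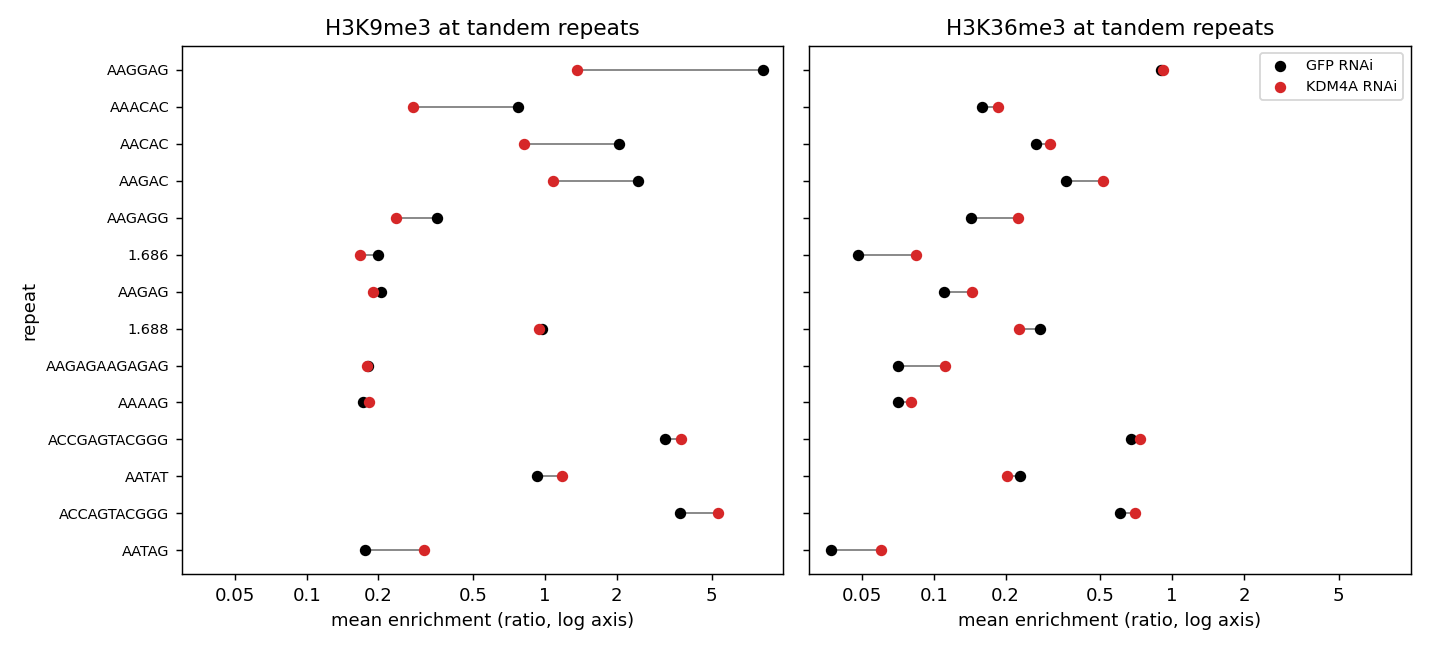
Mean enrichment (x axis, ratio on a log axis) of the 14 tandem repeats (y axis) after GFP RNAi (black) and KDM4A RNAi (red), for H3K9me3 (left) and H3K36me3 (right). Each point is 1 deposited mean without an error; AAGGAG is at 8.19 and 1.37 for H3K9me3 and at 0.896 and 0.911 for H3K36me3.

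The 4 satellites with the largest H3K9me3 decreases did not have lower H3K36me3. AAGGAG was at 0.896 and 0.911, AAACAC at 0.159 and 0.186, AACAC at 0.268 and 0.306, and AAGAC at 0.359 and 0.512. Among the 14 tandem repeats, 8 had lower H3K9me3 and higher H3K36me3, 4 had more of both, 1 had less of both and 1, AATAT, had higher H3K9me3 and lower H3K36me3. Across the 14, Pearson's r of the log2 ratios was 0.11 and Spearman's rho -0.02.

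Over the 185 other repeats, whose names were identical in both tables, the changes of the 2 marks were positively correlated across repeats (Pearson's r = 0.54, Spearman's rho = 0.52). The direction as deposited was often opposite: 76 had higher H3K9me3 and lower H3K36me3, 8 the reverse, 47 were higher in both and 52 lower in both. After centring these numbers were 26, 31, 81 and 47. Without the 2 repeats farthest from the median H3K9me3 change, r was 0.49. GYPSY11_LTR, FROGGER_LTR and R1-2_DM were higher in both marks, with H3K36me3 values of 0.750 and 0.864 at FROGGER_LTR and 0.904 and 1.11 at R1-2_DM. GYPSY3_LTR was lower in both, with H3K9me3 at 3.10 and 2.48. The internal parts of these LTR elements followed in only 1 of the 2 marks. GYPSY11_I was lower in H3K9me3 (1.90 and 1.85), FROGGER_I lower in H3K36me3 (1.05 and 0.995) and GYPSY3_I higher in H3K9me3 (3.41 and 3.52). Adding the 14 tandem repeats brought r to 0.05 and rho to 0.38. Repeats are not independent. The labels list 2 input libraries per treatment and no separate ones per antibody. Both marks would therefore draw on the same inputs if input was the denominator, which is not stated. Shared controls give a positive correlation with no effect at all, and the tables hold no input values to simulate its size.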

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

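Leaving out the tandem repeats, adding them to the correlation, centring for the medians per type and for the directions of both marks, and leaving elements out of the covariance were chosen after seeing the data. No paired analysis was possible because the tables hold 1 mean per treatment, which also rules out leaving out a replicate; weighting by length, leaving out chromosome arms and matching by overlap need coordinates and were not run. Without replicates there is no spread to set a change of setting against, so the changes are given as values, and their cause was not tested except where a setting only removes repeats. A pseudocount of 1 and the linear scale cannot change which column is larger, so the numbers of higher and lower repeats say nothing about them. With only repeats at or above the median level, 84 repeats were higher and 18 lower in H3K9me3, and 37 and 63 in H3K36me3. At 1.5 times or more the numbers were 1 and 5 in H3K9me3, and 5 and 0 in H3K36me3. Centring made them 113 and 90 in H3K9me3, and 124 and 75 in H3K36me3, which reverses the majority for H3K36me3. It subtracts 1 constant from all log2 ratios of a mark, 0.031 for H3K9me3 and -0.089 for H3K36me3. The H3K36me3 constant is larger in size than the median log2 ratio of -0.054, so this reversal follows from the shift. It does not show which direction is right, since the scaling for depth is unknown. The median log2 ratio of H3K9me3 (0.043) became 0.001 as a mean, 0.032 as a ratio of sums, 0.028 with a pseudocount of 1, 0.086 at or above the median level and 0.047 without the tandem repeats. That of H3K36me3 (-0.054) became -0.030, -0.037, -0.025, -0.039 and -0.059. Means per type for H3K9me3 were -0.395 for tandem repeats, 0.018 for LTR and 0.040 for DNA transposons; for H3K36me3 they were 0.297, -0.055 and -0.067, and -0.056 for histone genes. Centred medians per type for H3K9me3 were -0.104 (tandem), 0.015 (LTR), 0.043 (non-LTR), 0.040 (DNA), -0.157 (telomeric), 0.083 (histone) and 0.000 (ribosomal DNA). For H3K36me3 they were 0.304 (tandem) and -0.019 (histone), with the direction reversed for LTR (0.029), non-LTR (0.036), DNA (0.014), telomeric (0.064) and ribosomal DNA (0.045). The difference between the top and bottom of 4 level bins in H3K9me3 (0.199) was 0.094 with 2 bins and 0.164 without tandem repeats, and in H3K36me3 (0.056) it was 0.035 and 0.090. The correlation of the marks (r = 0.536, rho = 0.520) was 0.051 and 0.384 with the tandem repeats added, and 0.493 and 0.506 without the 2 farthest repeats. Of its 185 repeats, 76 had higher H3K9me3 and lower H3K36me3, 8 the reverse, 47 were higher in both and 52 lower in both; after centring the numbers were 26, 31, 81 and 47. The covariance of the marks in terminal minus internal parts (0.0164) was 0.00938 without GYPSY11 and 0.0056 without GYPSY11 and GYPSY3. A pseudocount of 1 shrank the log2 ratio by over 1.5 times, by its construction, in 11 of 22 named repeats for H3K9me3 and 16 of 21 for H3K36me3. For H3K9me3 AAACAC went from -1.467 to -0.471, AACAC from -1.322 to -0.743, AAGAC from -1.193 to -0.738 and AATAG from 0.817 to 0.156, while AAGGAG was at -1.958. For H3K36me3 1.686 went to 0.049, AATAG to 0.032, AAGAGG to 0.10 and AAGAGAAGAGAG to 0.053. Of 86 values of single named repeats under a pseudocount or centring, 6 changed direction, all under centring: G7_DM for H3K9me3 (-0.023), and HeT-A (0.051), TAHRE (0.043), TART (0.077), TART_B1 (0.086) and ribosomal DNA (0.045) for H3K36me3. The depth behind every value is unknown.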

Other observations

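The explanations below were all tested only after the tables had been seen. The 2 marks ranked the repeats only partly alike in GFP RNAi cells (Spearman's rho of their levels = 0.33 across 199 repeats). Pearson's r of the log2 levels was higher, at 0.56. Telomeric retrotransposons stood at opposite ends of the 2 tables: TART_B1 ranked 1 of 199 for H3K36me3 and 184 of 203 for H3K9me3, and TART ranked 2 and 187. HeT-A ranked 27 and 186. AAGGAG ranked 1 for H3K9me3 and 101 for H3K36me3. The satellites AAAAG, AAGAG, AATAG, 1.686 and AAGAGAAGAGAG had values of 0.172 to 0.205 for H3K9me3 and 0.037 to 0.110 for H3K36me3, below every transposon in GFP RNAi cells.

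R1_DM and R2_DM, elements that insert into ribosomal RNA genes, and R1-2_DM, a relative of R1, had more H3K9me3 than the ribosomal DNA row itself. R1_DM was at 3.57, R1-2_DM at 3.46 and R2_DM at 2.81 in GFP RNAi cells, against 1.67 for ribosomal DNA. All 3 were higher after KDM4A RNAi, at 3.82, 4.61 and 3.12, as were most repeats of similar level. In the level bin of R1_DM and R1-2_DM 46 of 51 repeats were higher, and in that of R2_DM 37 of 50. For H3K36me3 R1_DM was at 0.638, R1-2_DM at 0.904 and R2_DM at 0.580 in GFP RNAi cells, against 0.330 for ribosomal DNA. Within LTR retrotransposons, internal parts exceeded their terminal repeats in 35 of 51 elements for H3K9me3 and 34 of 51 for H3K36me3 in GFP RNAi cells.

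The lower H3K9me3 at AAGGAG, AAACAC, AACAC and AAGAC was weighed against 3 technical explanations. A change in a denominator shared by both antibodies, such as more input DNA of these repeats, would lower H3K36me3 alike. The median H3K36me3 log2 ratio of the 4 was 0.21 (range 0.02 to 0.51, SD over all repeats 0.18) where -1.19 or less was needed. AAACAC, AACAC and AAGAC had low H3K36me3 in GFP RNAi cells, 0.159 to 0.359, which left less room for a fall. AAGGAG was at 0.896 and 0.911. The AAGGAG values argue against a changed denominator if both marks share it, and those of the other repeats are weaker evidence. Base composition stays open: the 3 other repeats in the same range of G+C (33.3 to 50.0%) had H3K9me3 log2 ratios of -0.57 (AAGAGG, 0.351 and 0.237, with the same 50.0% G+C as AAGGAG), -0.11 (AAGAG) and -0.01 (AAGAGAAGAGAG), none as low as the -1.19 or less of the 4, and all 3 had low levels, 0.180 to 0.351. One library among those averaged also stays open, since if 2 libraries entered each mean a single GFP RNAi library at 15.01 for AAGGAG may give the difference, and the tables hold no values per library. An effect of KDM4A depletion on these satellites remains an untested hypothesis.

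The log2 ratios of the 2 marks were correlated over the 185 repeats other than satellites (r = 0.54). As deposited 76 of these had higher H3K9me3 and lower H3K36me3, and after centring 26. A denominator shared by both antibodies is a candidate explanation, because its noise would be larger in short terminal repeats than in internal parts of the same elements. In the 51 elements with both parts the covariance of the log2 ratios was 0.0206 in terminal repeats and 0.00419 in internal parts, a difference of 0.0164 (bootstrap over elements, 95% interval 0.0022 to 0.035), in the direction this explanation needs. Much of it came from a pair of elements: the difference was 0.00938 (0.00062 to 0.02) without GYPSY11 and 0.0056 (-0.0009 to 0.013) without GYPSY11 and GYPSY3, so the support is weak. Any other noise common to both marks, or real changes of both marks at single families, would also give a positive covariance, and the tables hold no lengths or read counts to separate them. A shared denominator would apply to the satellites too, but across the 14 tandem repeats r was 0.11 and rho -0.02. The noise of their denominator is unknown, so these values do not decide the question.

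H3K9me3 differences increased with the level of the mark, also without the tandem repeats (Spearman's rho = 0.45, bootstrap 95% interval over the 189 repeats 0.31 to 0.56). One scaling factor between the treatments would give no such relation, so these values argue against it as the whole explanation. A different enrichment contrast of the H3K9me3 libraries, in which a cleaner precipitation raises enriched repeats and lowers depleted ones, may account for the relation. The major-axis slope of the log2 values was 1.09 (95% interval over repeats 1.06 to 1.13). Of 23 repeats under a level of 1, 17 were lower, and 120 of 166 others were higher. The slope restates the increase with level, and the split at 1 largely does, so neither value is separate support for this explanation. A gain of H3K9me3 at marked transposons after KDM4A depletion would give the same slope and cannot be separated from contrast without a spike-in or values per library.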
